A study of Mus musculus with 12 samples.

How the data were processed

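RNA of mouse liver hepatocytes, macrophages and sinusoidal endothelial cells (SEC) from DEN-treated and untreated male C57Bl/6 mice was measured on 12 Illumina mouse bead arrays, 2 for each of 6 groups. Per the labels' protocols, mice received 25 mg/kg DEN intraperitoneally on postnatal day 25 and were followed for 9 months, total RNA was taken up with a column kit, and biotin-labelled cRNA was made with an Illumina TotalPrep kit. Per the labels, the RNA of DEN-treated mice was pooled from 3 to 4 animals, and how the cell types were isolated is not given in the sources used here. The table of values deposited by the authors is on a log2 scale, as read from its values, and was made with lumi per the submitters' processing notes, whose version and transform are not given in the sources used here. The transform may be log2 or lumi's log2-like variance-stabilising transform, so differences of dim probes can be compressed. The 12 arrays share nearly the same distribution (minimum 7.19, median 7.41 and maximum 15.19 on each), so the authors scaled the arrays to one another, and the values are neither centred per gene nor background-subtracted. The maximum of 15.19 limits the changes of the most abundant transcripts. The deposited non-normalized table has 24 columns, 12 of them signals, whose names match no sample label, and it was not used.

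Before the data were examined, the design fixed a fit on the non-normalized signals and, as the fallback, the same fit on the deposited values, which was used. The planned filter on detection p was replaced, after the files were seen, by one on receptor probes: a probe counted as above background on an array if it lay above the 95th percentile of 1501 probes for olfactory and vomeronasal receptors, genes that liver cells are not known to express, and was kept if this held on both arrays of at least 1 of the 6 groups. Of 45281 probes 34885 had 1 gene symbol, 18 several and 10378 none, and 34807 were named through their Entrez ID, 11 through an accession and 67 by the platform's symbol, with 10 symbols updated, from a gene table of assembly GRCm38.p6 used for names only. Of the 24155 probes above background, the probe with the highest mean over the 12 arrays stood for each gene, which left 12462 genes. The number of probes above background per array was 14768 and 14260 in DEN hepatocytes, 15939 and 16128 in untreated hepatocytes and up to 21552 in SEC. Replicates of a group correlated across genes with r between 0.991 (DEN hepatocytes) and 0.998, and the SD of their differences was 0.14 in untreated and 0.18 in DEN hepatocytes and 0.08 to 0.10 in the other groups, on the log2 scale.

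limma 3.58.1 in R 4.3.3 fitted the 6 group means with lmFit and eBayes (6 residual degrees of freedom), the tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 12462 genes, at a threshold of 0.05. The contrasts were DEN minus untreated in each cell type, the differences of these between cell types, and the differences between untreated cell types, the last also asked for at least 2-fold. limma's camera, with a preset correlation of 0.01, tested 43 lists fixed before the data were examined, 12 of cell type markers and 31 of other genes, each with at least 5 measured members, adjusted over the 43 lists of a cell type. Beside it stood camera with an estimated correlation, and fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. With fry 43 lists passed in hepatocytes, 37 in macrophages and 28 in SEC. The adjusted p with an estimated correlation is given where a call was lost with it, and beside some other calls. It was also higher for lists that kept their call, so very low values rest on the preset correlation. Overlaps were tested with Fisher's exact test over genes. In the figures Python 3.11.15 and matplotlib 3.10.9 were used.

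Named genes follow a rule fixed before the data were examined: per cell type the 10 largest passing rises and falls whose higher group lay above background, without predicted gene models, up to 4 passing members per list with the largest change, a preset group of genes given whatever their result, and for the interactions the 5 largest in each direction. A gene whose lower group was below background on both arrays has its fold computed against the background value and given as at least that number. The marker lists were those of hepatocytes, Kupffer cells, monocytes and monocyte-derived macrophages, SEC, vascular endothelium, stellate cells and fibroblasts, cholangiocytes, T and NK cells, B and plasma cells, neutrophils, dendritic cells, and erythroid cells and platelets. The gene lists covered oncofetal and DEN tumour genes, p53 targets, the cell cycle, P450 and phase I, glutathione, NRF2 and phase II, male-biased and female-biased, pericentral and periportal genes, bile acid and cholesterol synthesis, fatty acid synthesis and oxidation, gluconeogenesis with the urea cycle and amino acid catabolism, glycolysis and hypoxia, acute phase, interferon, NF-kB and cytokines, chemokines, MHC class II, alternative activation, lipid-associated macrophages and lysosomes, complement and phagocytosis, angiogenesis, angiocrine factors, extracellular matrix, TGF-beta, Notch and Wnt, immediate early and isolation stress genes, the unfolded protein response, oxidative phosphorylation and ribosomal proteins. The median, mean and test of a list differed in sign for 0 lists in hepatocytes, 7 in macrophages, none of which passed, and 6 in SEC, 1 of which passed.

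The fit was tested on simulated data of the same size. They were drawn with 1 spread per gene in all groups, and independently for each gene. Replicates of the real arrays differed more in hepatocytes than in the other groups. The rates below therefore test the fit under its own assumptions and are not error rates of these data. Of 50 genes changed by 0.25 on the log2 scale, 32% were recovered in hepatocytes, 22% in macrophages and 44% in SEC, at 0.5 these were 100%, 94% and 98%, and at 1 and 2 all were 100%. False calls made up 3.49%, 1.25% and 6.04% of the calls, the list that was shifted was called in each comparison, and 0, 0 and 1 other lists were. Alternatives tried were other filters and none, all probes in place of 1 per gene, an intensity trend with robust variance, array weights, a fit on the arrays compared only, replicate number as a block, leaving out each array in turn, a 2-fold threshold, and, added after the data were seen, a stricter receptor filter, background subtraction (the median receptor signal of the array removed, then an offset of 16), cyclic loess within each cell type and genes highest in the untreated cell type. No pairing by replicate number was seen: residuals of replicates with the same number correlated between -0.06 and 0.08 over 15 pairs of groups, with 0 pairs above 0.1. This does not exclude that arrays with the same number came from the same mice. Groups of 2 arrays are too small for a test of outlying arrays or of other splits of the samples. Probes without a gene name were counted but not described, and genome coordinates were not used here.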

Results

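RNA was measured on Illumina mouse bead arrays in 3 cell types isolated from the liver: hepatocytes, macrophages and sinusoidal endothelial cells (SEC), which line the liver's capillaries. The male C57Bl/6 mice had received 25 mg/kg of diethylnitrosamine (DEN), a carcinogen that hepatocytes activate, on postnatal day 25 and were followed for 9 months, or were untreated and of the same age. Each of the 6 groups held 2 arrays, and the RNA of DEN-treated mice was pooled from 3 to 4 animals. On each array 14260 to 21552 probes lay above background, and the median SE of a DEN change was 0.07 on the log2 scale. Changes are log2 differences, DEN minus untreated, ± SE with n = 2 arrays per group, and levels are deposited log2 values ± SD. The SE of a gene rests on 1 spread shared by all 6 groups, so it is the same in each cell type. Replicates differed more in hepatocytes (SD of differences 0.14 untreated and 0.18 DEN) than in SEC (0.08 in both). The SE may therefore be too small in hepatocytes and too large in SEC. The labels do not say whether the arrays of a group came from separate pools, so the p-values measure only the spread between these arrays, which may be technical. Where a fold is given as at least a number, the lower group lay below background on both its arrays. Where a count over a list adjusted over the list alone equals the count over all genes, only 1 of them is given.

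The untreated preparations carried the transcripts of their cell types. In hepatocytes the apolipoprotein gene Apoa1 reached 14.75 ± 0.03 and the thyroxine carrier Ttr 14.43 ± 0.04. They stood at 10.39 ± 0.02 and 11.23 ± 0.08 in macrophages and 9.15 ± 0.01 and 10.10 ± 0.10 in SEC. Macrophages had the highest levels of the Kupffer cell lectin Clec4f (14.33 ± 0.09) and the complement receptor Vsig4 (15.15 ± 0.05). SEC had the highest of the scavenger receptor Stab2 (13.32 ± 0.05) and the hyaluronan receptor Lyve1 (12.28 ± 0.04). All 20 hepatocyte markers were higher in hepatocytes than in macrophages (median 19.8-fold) and than in SEC (38.8-fold). All 16 Kupffer cell markers were higher in macrophages than in hepatocytes (25.8-fold). Their difference from SEC was 2.23-fold, with 13 higher and 1 lower, and Clec4f reached 13.39 ± 0.06 in SEC. Of 21 SEC markers 20 were higher in SEC than in hepatocytes (23.7-fold) and 20 higher than in macrophages (3.55-fold). By limma with Benjamini-Hochberg adjustment, 2644 of 12462 genes differed at least 2-fold between untreated hepatocytes and macrophages (1204 higher in hepatocytes). Between hepatocytes and SEC 2967 differed (1265 higher in hepatocytes), and between macrophages and SEC 1122 (482 higher in macrophages). With the background of each array subtracted first, these counts were 5207, 5726 and 2510.

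**Figure D1:**
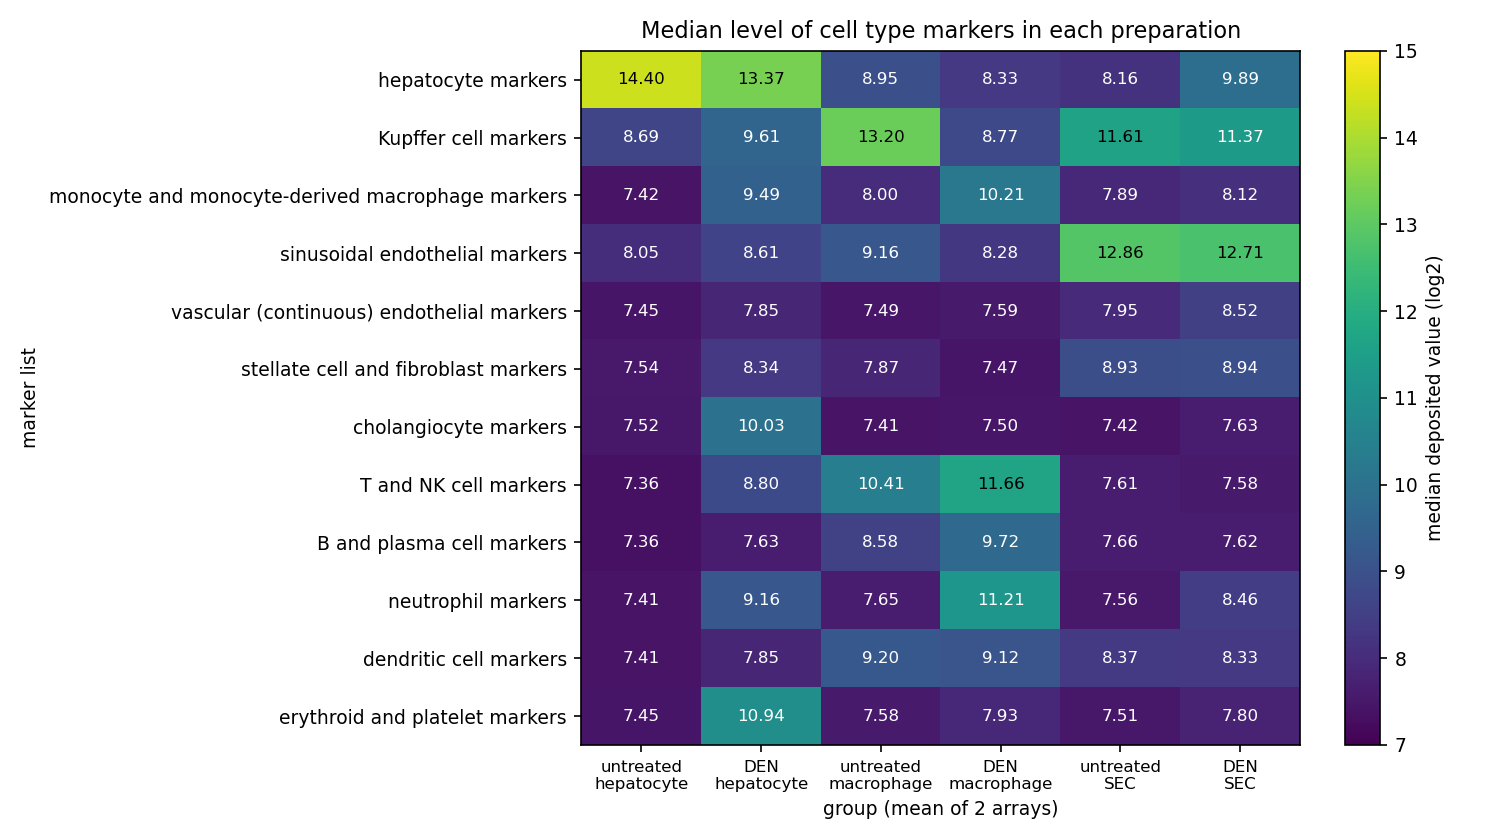
Each cell gives the median over a list of cell type markers of the mean deposited log2 value of 2 arrays, for each of the 6 preparations. Hepatocyte markers had their highest median in untreated hepatocytes (14.40), Kupffer cell markers in untreated macrophages (13.20) and SEC markers in untreated SEC (12.86), while in DEN macrophages the Kupffer cell median was 8.77.

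The comparison of DEN with untreated hepatocytes asks how the parenchymal cells of DEN-treated mice differ from those of untreated mice. Fetal and tumour-associated genes rose: the fetal serum protein Afp by 1.81 ± 0.08, the cell-surface proteoglycan Gpc3 at least 16.8-fold and the cyclin Ccnd1 by 2.84 ± 0.06 (adjusted p = 1.48e-11). Genes of the differentiated hepatocyte fell, led by the carbonic anhydrase Car3 (-5.41 ± 0.20, adjusted p = 1.07e-09). Next came the male-biased enzymes Cyp4a12a (-5.16 ± 0.06) and Hsd3b5 (-4.90 ± 0.07), and Cps1 (-4.61 ± 0.10), the first enzyme of the urea cycle. The largest rise was that of the globin Hba-a1 (7.03 ± 0.10, from 8.07 ± 0.26 to 15.09 ± 0.03). It was followed by the globins Hbb-bt (128-fold) and Hbb-bs (6.90 ± 0.13), the protease inhibitor Slpi (6.43 ± 0.06) and the serum amyloid Saa3 (6.13 ± 0.05). Then came the neutrophil proteins S100a8 (at least 53.2-fold) and S100a9 (at least 42.3-fold) and the interferon gamma receptor chain Ifngr2 (5.44). Blood cell genes among the largest rises were the platelet chemokine Pf4 (at least 34.9-fold) and the red cell anion exchanger Slc4a1 (at least 30.4-fold). Further falls were those of Keg1 (-4.50), Cyp4a12b (-4.28), Sult2a8 (-4.15) and Cyp2f2 (-4.11), the bile acid hydroxylase Cyp8b1 (-4.16) and Cth (-3.98), an enzyme of cysteine synthesis.

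Markers of most other liver and blood cells rose with these changes in the DEN hepatocyte preparation. The erythroid and platelet list had 8 of 8 measured members higher (adjusted p = 1.07e-05 by limma's camera), including Alas2 (2.12), the first enzyme of erythroid haem synthesis. The neutrophil list had 11 of 13 measured members higher (adjusted p = 5.15e-07, and adjusted p = 0.0424 with an estimated correlation), with myeloperoxidase, Mpo (at least 24.6-fold higher) and Lcn2 (4.64). The monocyte list had 9 of 13 measured members higher (adjusted p = 7.52e-05), with lysozyme, Lyz2 (4.91), S100a6 (at least 18-fold higher) and Chil3 (at least 13.6-fold higher). T and NK cell markers had 9 of 12 measured members higher (adjusted p = 6.06e-05), such as Ccl5 (3.99) and Cd3d (at least 5.44-fold higher). B and plasma cell markers had 6 of 8 measured members higher (adjusted p = 0.0189, and adjusted p = 0.0651 with an estimated correlation), such as Cd79b (at least 3.95-fold higher). Cholangiocyte markers had 8 of 8 measured members higher (adjusted p = 0.000244, and adjusted p = 0.11 with an estimated correlation), such as Tspan8 (at least 22.5-fold higher), Muc1 (at least 3.12-fold higher) and Krt7 (at least 2.51-fold higher). Stellate cell markers had 12 of 17 measured members higher and 1 lower (adjusted p = 0.000443, and adjusted p = 0.0584 with an estimated correlation), such as Acta2 (3.16) and Dcn (2.06). SEC markers had 10 of 21 measured members higher and 2 lower (adjusted p = 0.00922). Vascular endothelial markers had 9 of 13 measured members higher and 1 lower (adjusted p = 0.00411). Stab2 was at -0.05 ± 0.08 (adjusted p = 0.648). Of 16 Kupffer cell markers 8 were higher and 4 lower (adjusted p = 0.0732). The macrophage receptor Adgre1 (3.59) and the complement chain C1qb (3.04) rose, and Clec4f (-0.57) fell. Dendritic cell markers had 5 higher and 0 lower of 11 (adjusted p = 0.0625), with Siglech (3.51), and passed with background subtracted (7 higher and 0 lower, adjusted p = 0.0381). Hepatocyte markers had 15 of 20 measured members lower (1 higher and 15 lower adjusted over the list alone) (adjusted p = 0.000324), with Ass1 (-3.40), Hpd (-2.89) and Pck1 (-2.34). With cyclic loess within each cell type 5 of the same 20 were higher and 11 lower (adjusted p = 0.00993).

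Lists of hepatocyte metabolism fell beside these marker changes. Gluconeogenesis, urea cycle and amino acid catabolism had 24 of 24 measured members lower (adjusted p = 2.82e-11), including the glucose-releasing phosphatase G6pc (-3.43) and the methyltransferase Gnmt (-3.60). Bile acid and cholesterol synthesis had 20 of 22 measured members lower and 1 higher (adjusted p = 1.39e-07). The rate-limiting Cyp7a1 (-2.28), Cyp7b1 (-3.24), the bile salt pump Abcb11 (-3.69) and the conjugating enzyme Baat (-3.04) fell. Fatty acid synthesis had 20 of 23 measured members lower (21 passing adjusted over the list alone) (adjusted p = 1.39e-07), such as Thrsp (-3.87) and Acacb (-2.26). Fatty acid oxidation had 15 of 20 measured members lower and 1 higher (adjusted p = 0.000218), such as Acaa2 (-3.61) and Ehhadh (-2.35). Oxidative phosphorylation had 32 of 33 measured members lower (adjusted p = 7.7e-10), such as Cyc1 (-2.32) and Sdhb (-2.12). Male-biased hepatocyte genes had 15 of 16 measured members lower and 1 higher (adjusted p = 6.7e-07), such as Nudt7 (-3.77). Female-biased genes had 6 higher and 2 lower of 10 (adjusted p = 0.0833), with the steroid hydroxylase Cyp2a4 (4.94) and Cyp2b9 (at least 2.69-fold higher) among the risers. Cytochrome P450 and phase I genes had 26 of 30 measured members lower and 4 higher (adjusted p = 4.93e-07, and adjusted p = 0.0721 with an estimated correlation), including Cyp2e1 (-2.18), which activates DEN. Glutathione, NRF2 and phase II genes had 22 of 29 measured members lower and 6 higher (adjusted p = 0.000451, and adjusted p = 0.0954 with an estimated correlation), including Gstp1 (-2.83) and Gstm6 (-2.23). Periportal genes had 16 of 19 measured members lower and 2 higher (adjusted p = 3.48e-06). Pericentral genes had 10 of 15 measured members lower and 2 higher (adjusted p = 0.00928, and adjusted p = 0.392 with an estimated correlation), where Cyp27a1 (-2.97) fell and Glul (0.93), which makes glutamine, rose. Glycolysis and hypoxia targets had 10 higher and 7 lower of 21 (adjusted p = 0.29). Pkm (3.82) and Aldoa (1.61) rose and Pgk1 (-1.42) fell.

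Tumour, matrix and inflammatory lists rose in DEN hepatocytes, in the same arrays as the leukocyte and stromal markers. The oncofetal and DEN tumour list had 19 of 23 measured members higher and 2 lower (adjusted p = 1.39e-07), including S100a11 (4.19) and Cd63 (3.98), as well as Tspan8 and Lcn2. Leukocytes also make Lcn2 and Cd63. Cell cycle genes had 16 of 30 measured members higher and 5 lower (adjusted p = 0.0056, and adjusted p = 0.0721 with an estimated correlation), such as the replication factors Mcm6 (1.91) and Uhrf1 (at least 3.68-fold higher) and the mitotic gene Nusap1 (at least 3.43-fold higher). Extracellular matrix genes had 26 of 32 measured members higher and 1 lower (adjusted p = 9.34e-09), such as Timp2 (3.88), Sparc (2.55) and Col6a1 (at least 5.83-fold higher). TGF-beta targets had 16 of 21 measured members higher and 2 lower (adjusted p = 0.000157), such as Ccn2 (4.04) and Tgfbi (2.48). NF-kB and cytokine genes had 22 of 29 measured members higher and 1 lower (adjusted p = 5.53e-07), such as the neutrophil attractant Cxcl2 (at least 20.9-fold higher), Il1b (3.64) and Osm (at least 11-fold higher). Immediate early and isolation stress genes, which cell isolation is known to raise, had 24 of 28 measured members higher in the same arrays (adjusted p = 7.7e-10), such as Ier3 (4.31), Fos (at least 30-fold higher), Hspa1a (at least 17.8-fold higher) and Atf3 (at least 8.55-fold higher). Chemokines had 18 of 26 measured members higher and 1 lower (adjusted p = 8.06e-06). Tnf was at 0.12 ± 0.07 (adjusted p = 0.138). MHC class II and antigen presentation had 17 of 21 measured members higher and 2 lower (adjusted p = 7.52e-05), such as H2-Ab1 (3.24) and Ctss (3.03). Alternative activation had 16 of 24 measured members higher and 2 lower (adjusted p = 6.34e-05), such as Csf1r (2.21) and Mmp12 (at least 6.26-fold higher). Lipid-associated macrophage and lysosome genes had 16 of 25 measured members higher and 4 lower (adjusted p = 0.000218), such as Lgals3 (4.45), Lpl (3.67) and Gpnmb (at least 18.7-fold higher). Complement and phagocytic receptors had 19 of 24 measured members higher and 1 lower (adjusted p = 1.72e-06), such as Cfp (3.63) and Fcgr4 (3.20). Angiogenesis and endothelial activation had 23 of 33 measured members higher (24 passing adjusted over the list alone) (adjusted p = 7.27e-07), such as Ednrb (4.09), Flt1 (2.62) and Esm1 (at least 11-fold higher). Angiocrine factors had 15 of 24 measured members higher and 3 lower (adjusted p = 0.000433), where Cxcl12 (-2.13) fell. The acute phase list had 13 higher and 10 lower of 28 (adjusted p = 0.155), with the endotoxin receptor Cd14 (4.16) higher and the iron hormone Hamp (-2.49) lower. With cyclic loess it passed as higher (17 higher and 7 lower, adjusted p = 0.0301). The interferon list had 14 higher and 7 lower of 31 (adjusted p = 0.135), with Ifi27l2a (3.37) higher.

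In total 8433 of 12462 genes (67.7%) passed in hepatocytes, 3950 higher and 4483 lower, of which 1271 and 1084 changed at least 2-fold. With cyclic loess the split was 4208 higher and 4175 lower. Of the passing genes 46.8% were higher, 47.4% with background subtracted and 50.2% with cyclic loess. Of 43 lists 35 passed camera (24 up and 11 down), 27 of them also with an estimated correlation. All 177 passing genes named under the rule had both DEN arrays beyond both untreated arrays, which their passing in the same arrays nearly fixed. So had 2 of the 6 named genes that did not pass, and 78.6% of all genes, where chance gives 33.3% if the arrays are independent. Among the 4549 genes whose untreated level was highest in hepatocytes, 3716 passed, 573 higher and 3143 lower. These genes were chosen on the untreated arrays of the same comparison, which by construction favours falls.

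The macrophage comparison asks how the liver macrophages of DEN-treated mice differ from those of untreated mice. The largest rise was that of the neutrophil-attracting chemokine Cxcl2, by 6.12 ± 0.06 (from 7.77 ± 0.07 to 13.89 ± 0.08, adjusted p = 4.96e-13). Saa3 rose by 5.17 ± 0.05, the cytokine Osm by 4.96 ± 0.05 and the neutrophil gene Retnlg by 4.80 ± 0.05. Genes of resident Kupffer cells fell most, with Clec4f at -5.32 ± 0.07 (from 14.33 ± 0.09 to 9.02 ± 0.08, adjusted p = 1.01e-12). The haemoglobin scavenger receptor Cd163 (-5.21 ± 0.11), Vsig4 (-5.00 ± 0.06) and the folate receptor Folr2 (-4.99 ± 0.07) followed. The lipolysis inhibitor G0s2 (4.75), the decoy interleukin-1 receptor Il1r2 (4.72), the neutrophil gene Lcn2 (4.59) and the heat shock gene Hspa1a (4.57) were also among the largest rises. So were the mast cell chymase Cma2 (at least 23.1-fold) and the histamine-forming enzyme Hdc (4.45). The other large falls were C6 (-4.95), Gbp2b (-4.42), Timd4 (-4.36), Apoc1 (-4.35) and Pcolce2 (-4.28) and the hepatocyte-made urinary protein Mup2 (-4.49).

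All 16 measured Kupffer cell markers fell in macrophages (adjusted p = 8.23e-17 by camera). Their median level went from 13.20 to 8.77. It was 11.61 in untreated SEC and 11.37 in DEN SEC. Markers of other leukocytes and of blood cells rose in the same arrays. Neutrophil markers had 13 of 13 measured members higher (adjusted p = 5.14e-15), such as Ltf (3.77) and Camp (3.56). Monocyte markers had 11 of 13 measured members higher (adjusted p = 7.42e-09), such as Chil3 (4.03), Fn1 (2.37) and S100a4 (2.14) and the recruitment receptor Ccr2 (0.80). T and NK cell markers had 9 of 12 measured members higher (adjusted p = 2.03e-08), such as Ccl5 (1.98) and Nkg7 (1.93). B and plasma cell markers had 8 of 8 measured members higher (adjusted p = 1.68e-06), such as Mzb1 (2.31) and Blk (1.62). Erythroid and platelet markers had 6 of 8 measured members higher (7 passing adjusted over the list alone) (adjusted p = 0.000427), such as Pf4 (1.62). Markers of SEC, stellate cells and hepatocytes fell. SEC markers had 12 of 21 measured members lower and 1 higher (14 passing adjusted over the list alone) (adjusted p = 0.000124), such as Stab2 (-2.32) and Mrc1 (-2.90). Stellate cell markers had 11 of 17 measured members lower and 1 higher (13 passing adjusted over the list alone) (adjusted p = 0.000186, and adjusted p = 0.0605 with an estimated correlation), such as Dcn (-4.24) and Reln (-2.77). Hepatocyte markers had 11 of 20 measured members lower (13 passing adjusted over the list alone) (adjusted p = 0.000369, and adjusted p = 0.0605 with an estimated correlation), such as Trf (-2.02). Dendritic cell markers (5 higher and 2 lower of 11, adjusted p = 0.256) did not pass as a list. Nor did vascular endothelial (4 higher and 2 lower of 13, adjusted p = 0.714) or cholangiocyte markers (2 higher and 0 lower of 8, adjusted p = 0.26).

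NF-kB and cytokine genes had 23 of 29 measured members higher and 4 lower in macrophages (adjusted p = 2.26e-11), including Tnf (2.24) and Il1b (2.93). Immediate early and isolation stress genes had 24 of 28 measured members higher (25 passing adjusted over the list alone) in the same macrophage arrays (adjusted p = 5.34e-18), such as Hspa1a (4.57), Hspa1b (4.28) and Ier3 (2.80). Il6 was at -0.06 ± 0.05 (adjusted p = 0.405). Chemokines had 16 of 26 measured members higher and 6 lower (adjusted p = 0.000124), with Ccl3 (4.23) and Ccl4 (3.69) higher and Cxcl12 (-3.32) lower. Complement and phagocytic receptors had 18 of 24 measured members lower and 2 higher (21 passing adjusted over the list alone) (adjusted p = 7.42e-09), including C2 (-3.82) and Marco (-2.87). The alternative activation list had 15 of 24 measured members higher and 6 lower (22 passing adjusted over the list alone) (adjusted p = 0.00598). Arg1 (1.91), which degrades arginine, and Chil3 rose, whereas Cd163, Folr2 and Ccl24 (-3.14), also on the list, fell. Glycolysis and hypoxia targets had 11 of 21 measured members higher and 4 lower (19 passing adjusted over the list alone) (adjusted p = 0.00777), such as the angiogenic factor Vegfa (2.01) and the glucose transporter Slc2a1 (1.35). Glutathione, NRF2 and phase II genes had 16 of 29 measured members lower and 4 higher (21 passing adjusted over the list alone) (adjusted p = 0.00596, and adjusted p = 0.211 with an estimated correlation), such as the haem-degrading Hmox1 (-3.46) and Abcc3 (-2.76). Male-biased hepatocyte genes had 6 of 16 measured members lower (adjusted p = 0.00281), such as Mup3 (-3.10). Oxidative phosphorylation had 15 of 33 measured members lower (adjusted p = 0.0104, and adjusted p = 0.103 with an estimated correlation), such as Cox5a (-1.42), a call lost with cyclic loess (adjusted p = 0.0509). Lipid-associated macrophage and lysosome genes did not pass (9 higher and 11 lower of 25 (21 passing adjusted over the list alone), adjusted p = 0.736), although Gpnmb (4.30), Cd63 (3.20) and Trem2 (0.97) rose. Their median change was -0.18 and their mean 0.18. Nor did interferon genes (3 higher and 12 lower of 31 (17 passing adjusted over the list alone), adjusted p = 0.0988), with Gbp3 (-1.83) and Ifit3 (-1.57) lower. MHC class II and antigen presentation did not pass (6 higher and 8 lower of 21 (17 passing adjusted over the list alone), adjusted p = 0.891), with Cd86 (-1.64) lower and H2-Oa (1.45) higher.

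Several other lists did not pass in macrophages. Angiogenesis was one of them (6 higher and 15 lower of 33 (22 passing adjusted over the list alone), adjusted p = 0.0915), with Cdh5 (-3.78) lower and the chemokine receptor Cxcr4 (3.26) higher. Extracellular matrix genes (5 higher and 14 lower of 32, adjusted p = 0.136) and angiocrine factors (3 higher and 10 lower of 24, adjusted p = 0.0915) were others. With background subtracted the matrix list passed as lower (7 higher and 17 lower, adjusted p = 0.0417). In the acute phase list (8 higher and 11 lower of 28, adjusted p = 0.714) Socs3 (2.97) and Lrg1 (2.83) rose. In the cell cycle list (11 higher and 3 lower of 30 (15 passing adjusted over the list alone), adjusted p = 0.112) Tk1 (-1.02) and Ccnd1 (-0.83) fell. Oncofetal genes (9 higher and 5 lower of 23 (15 passing adjusted over the list alone), adjusted p = 0.0915) and TGF-beta targets (9 higher and 7 lower of 21 (17 passing adjusted over the list alone), adjusted p = 0.392) did not pass, although the oncofetal list passed as higher with background subtracted (adjusted p = 0.0216). The same held for P450 genes (2 higher and 8 lower of 30, adjusted p = 0.26) and bile acid and cholesterol synthesis (1 higher and 10 lower of 22, adjusted p = 0.1). It held for fatty acid synthesis (4 higher and 5 lower of 23, adjusted p = 0.736) and fatty acid oxidation (2 higher and 6 lower of 20, adjusted p = 0.246). It held for gluconeogenesis and amino acid genes (1 higher and 7 lower of 24, adjusted p = 0.274) and periportal genes (2 higher and 5 lower of 19, adjusted p = 0.629). With background subtracted, P450 genes (2 higher and 14 lower, adjusted p = 0.0197), bile acid and cholesterol synthesis (10 lower, adjusted p = 0.0197) and gluconeogenesis and amino acid genes (1 higher and 10 lower, adjusted p = 0.0417) passed as lower. Pericentral (0 higher and 5 lower of 15, adjusted p = 0.329) and female-biased genes (1 higher and 0 lower of 10, adjusted p = 0.543) did not pass either.

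In total 5353 genes (43.0%) passed, 2323 higher and 3030 lower, of which 359 and 464 changed at least 2-fold. With cyclic loess the split was 2691 higher and 2609 lower. The share of passing genes that were higher was 43.4%, 42.2% with background subtracted and 50.8% with cyclic loess. Of 43 lists 20 passed camera (12 up and 8 down), 16 of them also with an estimated correlation. All 158 passing genes named under the rule had both DEN arrays beyond both untreated arrays, which their passing in the same arrays nearly fixed. So had 7 of the 14 named genes that did not pass, and 74.8% of all genes, where chance gives 33.3% if the arrays are independent. Among the 3781 genes whose untreated level was highest in macrophages, a choice that also favours falls, 2249 passed (1052 higher and 1197 lower).

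**Figure D2:**
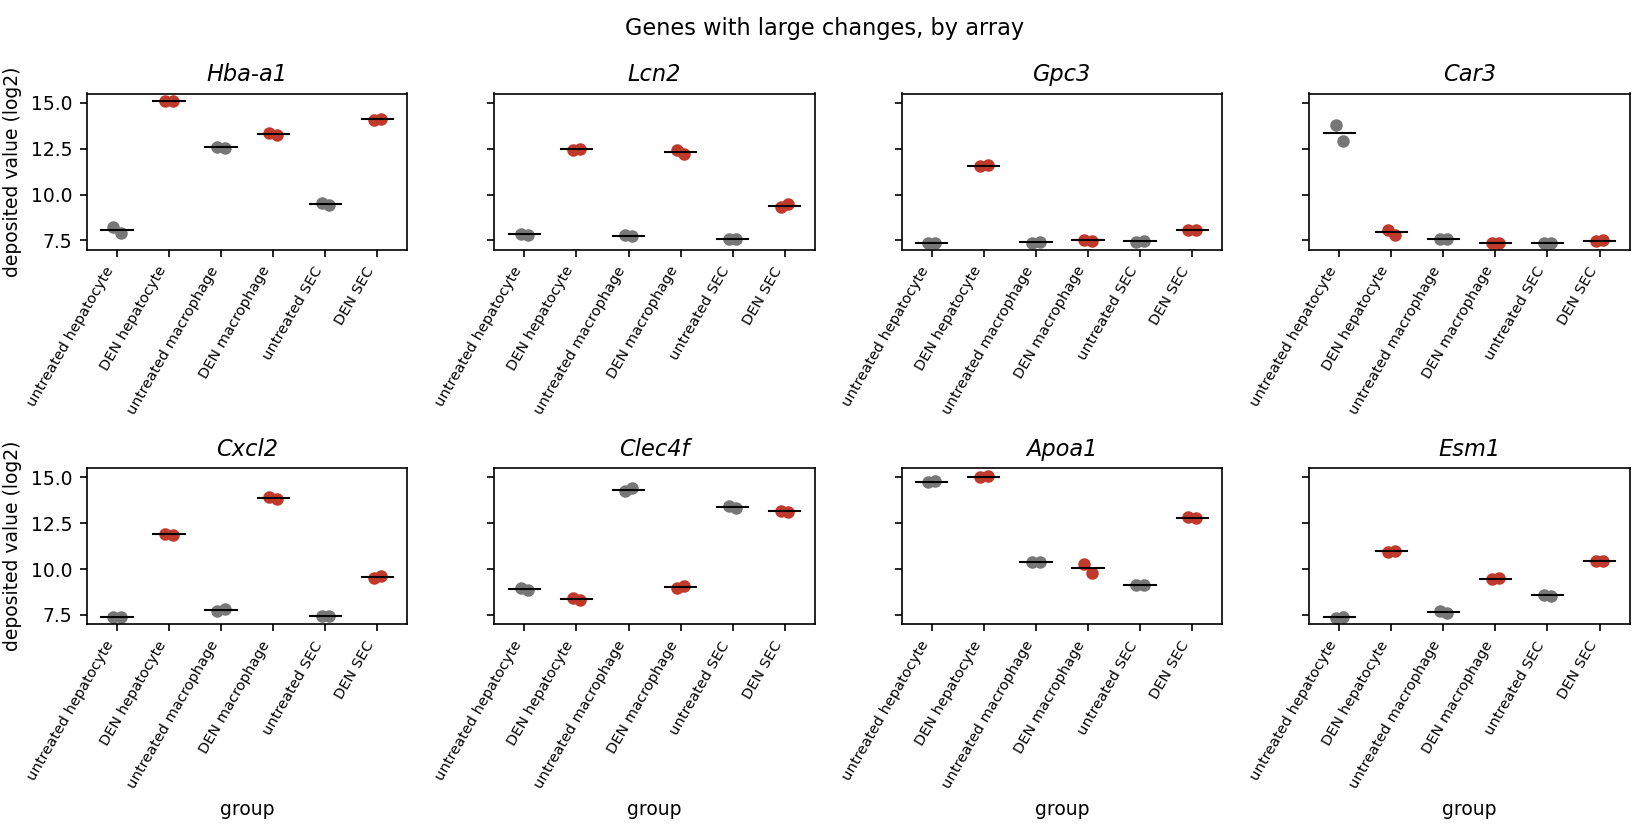
Each panel shows the deposited log2 value of 1 gene on each array (points, grey untreated and red DEN) and the mean of the 2 arrays of a group (line), for 8 genes chosen after their values were seen from those the text names. Clec4f had a mean of 14.33 in untreated and 9.02 in DEN macrophages, against 13.39 and 13.15 in SEC, and Apoa1 had 9.15 in untreated and 12.80 in DEN SEC.

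The SEC comparison asks how the sinusoidal endothelium of DEN livers differs from that of untreated livers. Its largest rises were the globins Hbb-bs (5.08 ± 0.13, from 9.62 ± 0.03 to 14.70 ± 0.00, adjusted p = 2.43e-09), Hbb-bt (4.66 ± 0.10) and Hba-a1 (4.59 ± 0.10). Next came plasma proteins of the hepatocyte, Apoa1 (3.65 ± 0.12), Ahsg (3.53 ± 0.07) and Kng1 (3.35 ± 0.09). Among endothelial genes the tip cell marker Esm1 rose by 1.86 ± 0.05 (adjusted p = 2.43e-09) and the clotting factor Vwf by 0.97 ± 0.05 (adjusted p = 4.22e-07). The identity genes Stab2 (0.04 ± 0.08) and Lyve1 (0.03 ± 0.09) and the diaphragm gene Plvap (-0.08 ± 0.08) did not pass (adjusted p = 0.977, 0.987 and 0.889). The mitochondrial gene ND4L (3.24) and Serpina1a (3.03), Ambp (2.87) and Apoa2 (2.86) were the other large rises. The largest falls were smaller: the kinase Btk (-0.85), the endoplasmic reticulum chaperone Pdia3 (-0.87), the lectin Clec2d (-0.91), Trappc3 (-0.81) and Gripap1 (-0.72), the phosphoinositide kinase subunit Pik3r1 (-0.70), Dnajc7 (-0.68) and Prkd3 (-0.67). The falls of Rab1a (-1.03) and Hmox1 (-0.68) no longer passed with background subtracted. Their adjusted p-values were then 0.0721 and 0.304, the highest over the alternatives, whose lowest were 9.12e-08 and 8.39e-06.

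Markers of other cells moved with DEN in the SEC preparation. Hepatocyte markers had 12 of 20 measured members higher (14 passing adjusted over the list alone) (adjusted p = 2.65e-39 by camera, and adjusted p = 0.00203 with an estimated correlation). Their median level went from 8.16 to 9.89, against 13.37 in DEN hepatocytes. Neutrophil markers had 8 of 13 measured members higher (9 passing adjusted over the list alone) (adjusted p = 5.79e-23, and adjusted p = 0.00575 with an estimated correlation), such as S100a9 (2.46), S100a8 (2.25) and Lcn2 (1.80). Erythroid and platelet markers had 4 of 8 measured members higher (adjusted p = 4.42e-08), such as Alas2 (at least 1.79-fold higher). Monocyte markers had 5 of 13 measured members higher (6 passing adjusted over the list alone) (adjusted p = 1.05e-06), such as S100a6 (0.78) and Fn1 (0.69). Cholangiocyte markers had 4 of 8 measured members higher (adjusted p = 2.54e-08, and adjusted p = 0.0492 with an estimated correlation), such as Tspan8 (at least 2.3-fold higher) and Krt8 (1.10). Krt8 also stood at 11.33 in untreated and 11.75 in DEN hepatocytes, and Tspan8 also rose in the DEN hepatocyte preparation. Whether these transcripts in SEC came from bile duct cells or from hepatocytes was not tested. Vascular endothelial markers had 2 of 13 measured members higher and 1 lower (6 passing adjusted over the list alone) (adjusted p = 0.000572), with Vwf and Fbln2 (at least 1.5-fold higher). Kupffer cell markers had 2 of 16 measured members lower (6 passing adjusted over the list alone) (adjusted p = 0.000202). Vsig4 (-0.37) lost its call with background subtracted (adjusted p = 0.124, range from 8.64e-05 over the alternatives). C1qb (-0.49) lost it when any 1 of the 4 SEC arrays was left out (adjusted p = 0.0923 to 0.167, range from 0.000457). SEC markers did not pass as a list (3 higher and 0 lower of 21, adjusted p = 0.358). The growth factor Wnt2 (0.76) lost its call with background subtracted (adjusted p = 0.126, range from 9.92e-06). Clec4g (0.28) lost it without replicate 2 of untreated or of DEN SEC (adjusted p = 0.258 and 0.259, highest 0.334). Flt4 (0.21) lost it without any SEC array but DEN replicate 2 (adjusted p = 0.162 to 0.324). With cyclic loess in place of the authors' scaling alone, the SEC marker list passed (adjusted p = 0.013). Stellate cell (3 higher and 0 lower of 17 (6 passing adjusted over the list alone), adjusted p = 0.339) and T and NK cell markers (1 higher and 0 lower of 12, adjusted p = 0.289) did not pass. Nor did B and plasma cell (0 higher and 0 lower of 8, adjusted p = 0.725) or dendritic cell markers (0 higher and 0 lower of 11, adjusted p = 0.988). At an unadjusted p under 0.05 limma gave 0 B and plasma cell and 1 dendritic cell marker.

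The acute phase list had 17 of 28 measured members higher in SEC (adjusted p = 1.04e-36, and adjusted p = 0.00291 with an estimated correlation). The members with the largest rises, Hpx (2.51), Hp (2.43), Fga (2.35) and Fgg (2.11), are plasma proteins that hepatocytes make. Other hepatocyte lists rose beside the hepatocyte markers. Male-biased genes had 6 of 16 measured members higher (adjusted p = 8.4e-08), such as Mup5 (1.49) and Mup20 (1.36). P450 and phase I genes had 8 of 30 measured members higher (9 passing adjusted over the list alone) (adjusted p = 2.45e-10, and adjusted p = 0.0594 with an estimated correlation), such as Cyp2a5 (2.77) and Cyp2e1 (1.51). Gluconeogenesis and amino acid genes had 4 of 24 measured members higher (8 passing adjusted over the list alone) (adjusted p = 1.31e-07), such as Mat1a (0.80). Periportal genes had 3 of 19 measured members higher (5 higher and 1 lower adjusted over the list alone) (adjusted p = 3.65e-05), such as Pigr (0.83). Pericentral genes had 2 of 15 measured members higher (3 passing adjusted over the list alone) (adjusted p = 0.000323, and adjusted p = 0.324 with an estimated correlation), such as Slco1b2 (1.02). Female-biased genes had 2 of 10 measured members higher (adjusted p = 0.00348), such as Cyp2a4 (at least 5.33-fold higher). Glutathione and phase II genes had 8 of 29 measured members higher and 1 lower (12 passing adjusted over the list alone) (adjusted p = 7.88e-06, and adjusted p = 0.0611 with an estimated correlation), such as Gsta3 (1.69). Extracellular matrix genes had 10 of 32 measured members higher (13 passing adjusted over the list alone) (adjusted p = 5.01e-13), such as Fbln1 (1.55), Col18a1 (0.92) and Col3a1 (0.74), the last of these made chiefly by fibroblasts and stellate cells. NF-kB and cytokine genes had 6 of 29 measured members higher (7 passing adjusted over the list alone) (adjusted p = 7.55e-07), such as Cxcl2 (2.12) and Cxcl1 (0.54). Immediate early and isolation stress genes had 8 of 28 measured members higher (10 passing adjusted over the list alone) in the same SEC arrays (adjusted p = 1.4e-10), such as Egr1 (1.33), Fos (0.98) and Hspa1a (0.80). Chemokines had 5 of 26 measured members higher (6 higher and 2 lower adjusted over the list alone) (adjusted p = 0.00348, and adjusted p = 0.0935 with an estimated correlation), such as Ccl3 (0.85). The oncofetal list had 5 of 23 measured members higher (7 passing adjusted over the list alone) (adjusted p = 9.56e-06), including Gpc3 (0.61), Tspan8 and Lcn2. Angiogenesis and endothelial activation had 6 of 33 measured members higher and 2 lower (12 passing adjusted over the list alone) (adjusted p = 0.00108), where the test and the mean (0.12) were up and the median was -0.01. Interferon genes, a list shifted down, had 0 of 31 members passing in limma and 8 lower at an unadjusted p under 0.05 (adjusted p = 0.0021, and adjusted p = 0.143 with an estimated correlation). Fatty acid synthesis passed up with 2 higher and 0 lower of 23 (adjusted p = 0.0185, and adjusted p = 0.0611 with an estimated correlation), with Scd1 (1.36). Glycolysis and hypoxia targets had 1 higher and 0 lower of 21 (adjusted p = 0.0236, and adjusted p = 0.0696 with an estimated correlation), a call lost with background subtracted (adjusted p = 0.0531).

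Among lists that did not pass in SEC were bile acid and cholesterol synthesis (1 higher and 0 lower of 22 (2 passing adjusted over the list alone), adjusted p = 0.358) and fatty acid oxidation (1 higher and 0 lower of 20, adjusted p = 0.391). Oxidative phosphorylation (0 higher and 1 lower of 33 (7 passing adjusted over the list alone), adjusted p = 0.194) and the cell cycle (1 higher and 0 lower of 30 (2 passing adjusted over the list alone), adjusted p = 0.339), with Mcm6 (0.45), were others. MHC class II and antigen presentation (0 higher and 1 lower of 21, adjusted p = 0.0776) and lipid-associated macrophage and lysosome genes (3 higher and 0 lower of 25 (6 passing adjusted over the list alone), adjusted p = 0.787) did not pass. Nor did alternative activation (3 higher and 0 lower of 24, adjusted p = 0.586), with Arg1 (0.72), or complement and phagocytic receptors (1 higher and 3 lower of 24 (6 passing adjusted over the list alone), adjusted p = 0.288), with Cfb (0.81). Angiocrine factors did not pass (2 higher and 0 lower of 24 (3 passing adjusted over the list alone), adjusted p = 0.339), and Hgf was at -0.10 ± 0.06 (adjusted p = 0.585). TGF-beta targets did not pass (0 higher and 0 lower of 21, adjusted p = 0.725), with 2 lower at an unadjusted p under 0.05 in limma.

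In total 443 genes (3.55%) passed, 319 higher and 124 lower, and of the 86 that changed at least 2-fold 85 were higher and 1, Rab1a, lower. Of 43 lists 26 passed camera (23 up and 3 down), 17 of them also with an estimated correlation. All 105 passing genes named under the rule had both DEN arrays beyond both untreated arrays, which their passing in the same arrays nearly fixed. So had 13 of the 24 named genes that did not pass, and 52.3% of all genes, where chance gives 33.3% if the arrays are independent. The share of passing genes that were higher was 72.0%, 91.6% with background subtracted and 86.0% with cyclic loess. The count was 809 with SEC arrays only in the model (473 higher and 336 lower) and 1278 with array weights, where more were lower than higher (606 higher and 672 lower). It was 281 (235 higher) and 278 (229 higher) without untreated replicate 1 or 2, and 284 (238 higher) and 292 (236 higher) without DEN replicate 1 or 2. It was 116 (56 higher and 60 lower) among the 4132 genes whose untreated level was highest in SEC, a choice that favours falls.

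**Figure D3:**
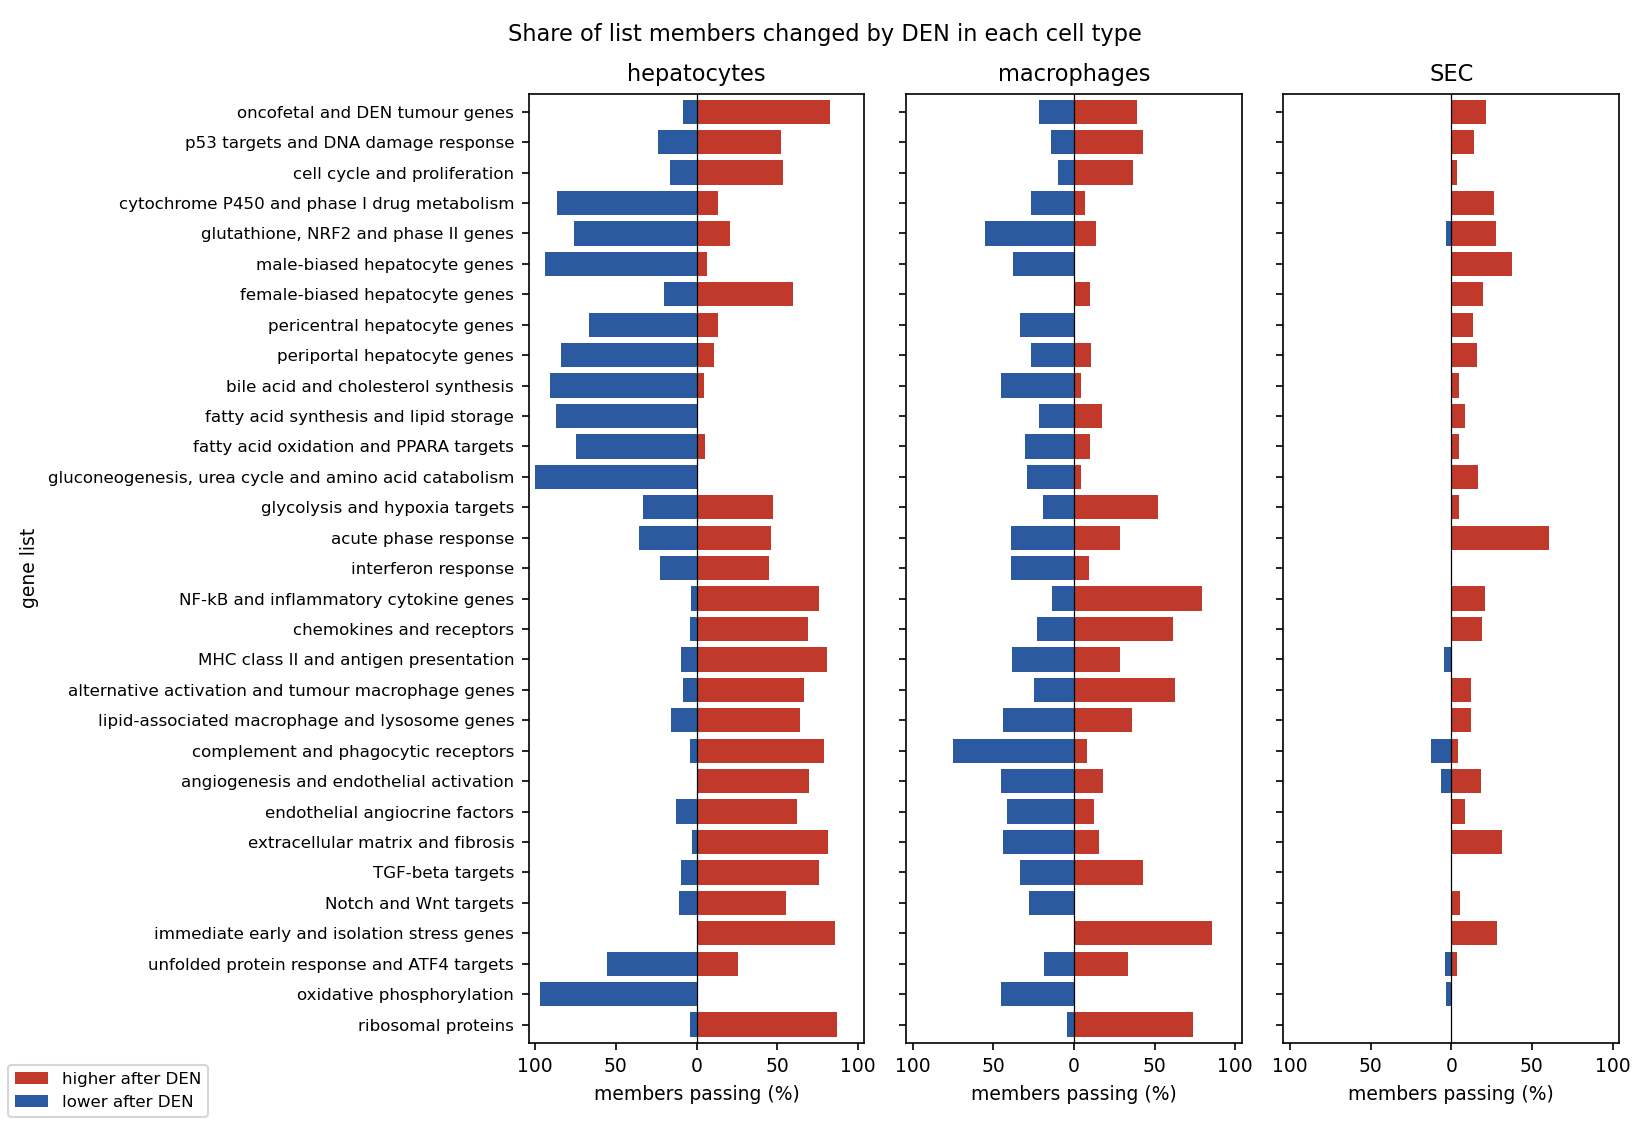
Bars give the share (percent) of the measured members of each of 31 gene lists that passed as higher (red, to the right) or lower (blue, to the left) after DEN in each cell type. In hepatocytes all 24 members of the gluconeogenesis, urea cycle and amino acid list were lower, in macrophages 24 of 28 immediate early genes were higher, and in SEC 17 of 28 acute phase genes were higher.

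The series asks for responses specific to a cell type, which the interaction test addresses by comparing the DEN change in one preparation with that in another, so that it includes other cells in each preparation. The matrix proteoglycan Dcn rose by 2.06 in hepatocytes and fell by 4.24 in macrophages, and the macrophage receptor Adgre1 rose by 3.59 and fell by 2.36. Most stellate cell markers moved with Dcn: of 17, 12 were higher and 1 lower in hepatocytes, and 11 lower and 1 higher in macrophages. All 16 Kupffer cell markers were lower in macrophages, as Adgre1 was. In hepatocytes 8 of them were higher and 4 lower, and the list did not pass (adjusted p = 0.0732 by camera). G0s2 changed by -1.87 in hepatocytes and 4.75 in macrophages (adjusted p = 5.77e-11). Car3 changed by -5.41 in hepatocytes and 0.13 in SEC, where its untreated level lay below background (adjusted p = 2.88e-08). Clec4f changed by -5.32 in macrophages and -0.25 in SEC (adjusted p = 7.15e-11). By limma with Benjamini-Hochberg adjustment, the DEN change differed between hepatocytes and macrophages for 7851 genes (3832 with the higher change in hepatocytes). It differed between hepatocytes and SEC for 7429 (3679 higher in hepatocytes) and between macrophages and SEC for 4111 (1911 higher in macrophages).

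Among the 83 genes that rose in all 3 cell types were the cytokine Il1b (3.64, 2.93 and 1.51), Lcn2 (4.64, 4.59 and 1.80), the globin Hba-a1 (7.03, 0.72 and 4.59) and the immediate early gene Egr1 (2.76, 2.05 and 1.33), in the order hepatocytes, macrophages and SEC. In SEC, Il1b lost its call with background subtracted (adjusted p = 0.0613, range from 6.52e-09 over the alternatives). Among the 22 genes that fell in all 3 were Clec2d (-0.67, -0.56 and -0.91) and Trappc3 (-0.51, -0.58 and -0.81). Hepatocytes and macrophages shared 1287 risers, where 736 would be shared if the lists were independent (odds ratio 3.49, adjusted p = 1.12e-152 by Fisher's exact test over genes, 6 tests). They shared 1323 fallers against 1090 (odds ratio 1.54, adjusted p = 2.83e-23), and 1407 genes changed in opposite directions against 1796. Hepatocytes and SEC shared 158 risers against 101 (odds ratio 2.16, adjusted p = 3.94e-11) and 33 fallers against 44.6 (0.643 and 0.0304). In opposite directions 189 genes changed against 154. Macrophages and SEC shared 101 risers against 59.5 (odds ratio 2.07, adjusted p = 1.73e-08) and 74 fallers against 30.1 (4.70 and 7.98e-17). In opposite directions 141 changed against 101. Genes are not independent replicates. Across genes, Pearson's r of the changes was 0.209 for hepatocytes and macrophages (rho 0.214). It was 0.0694 for hepatocytes and SEC (rho -0.0514) and 0.126 for macrophages and SEC (rho 0.171). The 33 fallers shared by hepatocytes and SEC became 64 and 63 without DEN hepatocyte replicate 1 or 2, 14 and 17 without untreated SEC replicate 1 or 2 and 16 without either DEN SEC replicate. The 74 shared by macrophages and SEC became 49 without untreated macrophage replicate 2, 29 and 33 without untreated SEC replicate 1 or 2 and 32 and 36 without DEN SEC replicate 1 or 2. The labels do not say whether cells of different types came from the same mice.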

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

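The test of Kupffer cell markers in the SEC preparation, the test against general myeloid genes, the test of erythroid genes against the other preparations and the tests of levels over the receptor probes were chosen only after the results they concern were seen, and the other tests of explanations were set before their values were.

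The DEN change differed between cell types by the interaction test of limma for 7851 genes between hepatocytes and macrophages, 7429 between hepatocytes and SEC and 4111 between macrophages and SEC. The largest differences, in log2 units of the first cell type's change minus the second's, were for hepatocytes minus macrophages Hba-a1 (6.31), Dcn (6.30), Hbb-bt (6.19), Hbb-bs (6.11) and Adgre1 (5.95), and in the other direction G0s2 (-6.61), Car3 (-5.20), Cyp4a12a (-5.04), Hsd3b5 (-4.72) and Cps1 (-4.34). For hepatocytes minus SEC they were Saa3 (5.75), Slpi (5.73), Pf4 (5.25), Ifngr2 (5.05) and Mt1 (4.89), and Car3 (-5.54), Cyp4a12a (-5.19), Hsd3b5 (-4.91), Cps1 (-4.65) and Keg1 (-4.62). For macrophages minus SEC they were Saa3 (4.80), Hdc (4.58), Cma2 (4.51), G0s2 (4.51) and Osm (4.46), and Mup2 (-5.37), Mup6 (-5.25), ND4L (-5.21), Cd163 (-5.12) and Clec4f (-5.07). These values are not measured sizes where a group lay below background on both its arrays: Pf4 in untreated hepatocytes, Cma2 in untreated macrophages and SEC, Car3 in DEN macrophages and untreated SEC, and Cyp4a12a, Hsd3b5 and Cps1 in DEN macrophages. The scale ends at 15.19, which limits the differences and ranks of Hba-a1, Hbb-bt and Hbb-bs, at 15.09, 15.05 and 15.16 in DEN hepatocytes. Probes without a gene name, which the comparisons leave out, also changed: of 4093 above background 2573 passed in hepatocytes (1573 higher), 1552 in macrophages (1067 higher) and 101 in SEC (79 higher).

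Leukocyte, erythroid, biliary and stromal genes rose in DEN hepatocytes while hepatocyte genes fell, and dilution of hepatocyte RNA as the whole cause of the fall is argued against by the unequal changes of 181 genes at least 16-fold higher in untreated hepatocytes than in the other untreated cells: their interquartile range was 1.82 (quartiles -2.66 and -0.84), and -2.80 to -1.08 among the 96 of them below a level of 13, away from the top of the scale. RNA of other liver cells in the preparation is a candidate explanation of the rise. Of 114 genes at least 16-fold higher in DEN macrophages than in untreated hepatocytes 100% passed as higher in DEN hepatocytes, against 31.7% of all genes. This test cannot decide it, because genes chosen for a low level in untreated hepatocytes had little room to fall. The share of all genes was not matched for that level. A rise of the same genes within hepatocytes would also give this result. The gain had a median of 30.2% (quartiles 15.17% and 49.5%) of the signal in DEN macrophages. In DEN macrophages S100a8, Lyz2 and Cxcl2 reached 14.16 ± 0.23, 13.85 ± 0.12 and 13.89 ± 0.08. For the erythroid and platelet genes, a carry-over of the macrophage and SEC preparations as captured is argued against as the only source. These genes lay 1.005 (median, quartiles 0.88 and 1.91) above the higher of DEN macrophages and DEN SEC. All 8 were higher, and the median was only just past the limit set for this test. The same blood cells at a larger share of the DEN hepatocyte preparation would also give this result and stay open. A background difference stays open for the dimmer risers: the median change of the receptor probes (0.00315) was fixed near 0 by the authors' scaling and decides nothing, their 99th percentile was 7.65 and 7.68 on the untreated and 7.87 and 7.83 on the DEN arrays, and the 63 passing leukocyte, erythroid, biliary and stromal markers lay a median of 1.43 (quartiles 0.70 and 3.80) above it in DEN hepatocytes. Whether such cells were infiltrating tumour tissue, adhering to hepatocytes or left by the isolation stays open and was not tested, as does any change within hepatocytes of genes that other cells also express.

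Kupffer cell markers fell in DEN macrophages by a median of -2.88 (16 of 16 lower; quartiles -4.96 and -2.37). In the DEN SEC preparation the same 16 markers changed by a median of -0.18 (quartiles -0.26 and -0.07, 2 of 16 lower, lowest -0.49). All lay above background there, at a median level of 11.6 without treatment. As a list they passed as lower (adjusted p = 0.000202 by camera). If that signal came from Kupffer cells, it argues against their loss, or lower expression of these genes in them, throughout the liver. Whether it came from Kupffer cells or from SEC was not tested, so neither is excluded. The labels do not say whether these preparations came from the same mice. Dilution by non-myeloid cells as the whole cause is argued against by 29 general myeloid genes. Their median change was -0.15 (quartiles -0.77 and 0.08, 14 lower and 5 higher), 2.73 above that of the Kupffer markers. Dilution as a part of the cause stays open, because other myeloid cells, whose markers rose in the same arrays, also express general myeloid genes. Background as the whole source of the lost signal is argued against by the level of the 16 markers in untreated macrophages, a median of 5.72 (quartiles 4.40 and 6.96) above the 99th percentile of the receptor probes, whose median change (0.000497) was fixed near 0 by the scaling and decides nothing. A change in which macrophages and granulocytes the preparation captured, or lower expression confined to the Kupffer cells that it captured, may each be the source, and both stay open, as does a difference in the yield of Kupffer cells: all 13 neutrophil and 11 of 13 monocyte markers rose in the same arrays, which fits the first, and no test here separates them.

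Plasma protein and other hepatocyte genes rose in DEN SEC. Background as the whole source of the rise is argued against by the level of the 12 passing hepatocyte markers in DEN SEC, a median of 3.84 (quartiles 3.19 and 5.17) above the 99th percentile of the receptor probes, whose median change (-0.00774) was fixed near 0 by the scaling and decides nothing. Carry-over of hepatocyte RNA is a candidate explanation. Of 79 genes at least 16-fold higher in both hepatocyte groups than in untreated SEC, 100% passed as higher in DEN SEC. Of all 12462 genes 319 did. The median gain of the 79 was 5.01% (quartiles 3.45% and 7.67%) of the signal in DEN hepatocytes. This test cannot decide it, because genes chosen for a low level in untreated SEC had little room to fall. A rise of the same genes within SEC would also give this result. In DEN SEC Apoa1 and Ahsg reached 12.80 and 12.61. Genes at least 16-fold higher in both hepatocyte groups than in untreated SEC made up 24.8% of those higher in DEN SEC, and carry-over was not tested for the others, Esm1 and Cxcl2 among them. Expression of the plasma protein genes by SEC themselves was not tested and stays open.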

How the results depend on the processing

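The stricter receptor filter, background subtraction, cyclic loess and the genes highest in the untreated cell type were chosen after the data were seen, as was the receptor filter itself. Settings named before the data were examined that need the unmapped signals were not run: no background correction, an offset of 50, median-centring, neqc per cell type and detection p under 0.01. The authors' values, named then as an alternative, are the values used. No named gene passed in the opposite direction under any alternative. Of the alternatives' values for named genes, 2581 of 2613 in hepatocytes, 2401 of 2477 in macrophages and 1624 of 1835 in SEC kept their side of the threshold, 24, 62 and 194 lost it, and 8, 14 and 17 gained it. Without any filter, with the stricter filter, with an intensity trend and robust variance and with a single replicate block, every total count of genes and lists stayed within 1.5 times its value. Without any filter the lists shifted down in macrophages went from 8 to 13. For results that moved, the cause was not tested unless the alternative's construction shows it. Signal over background bounds what was measured: 12462 genes had a probe above it.

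With all probes tested, which raises the number tested, the counts were 15479 in hepatocytes and 9280 in macrophages, 14458, 13503 and 6987 for the interactions of hepatocytes with macrophages, hepatocytes with SEC and macrophages with SEC, and 4149, 4557 and 1714 for the same pairs untreated, with shared risers and fallers of 2353 and 2176 (hepatocytes and macrophages), 252 and 50 (hepatocytes and SEC) and 173 risers (macrophages and SEC). At an adjusted p under 0.05 and at least 2-fold, a stricter criterion by construction, they were 2355, 823 and 86 in hepatocytes, macrophages and SEC, 2465, 2421 and 872 for the interactions, and 188 and 49, 24 and 0, and 13 and 0 shared risers and fallers in the same order of pairs. With only the arrays of the cell types compared, SEC had 809 genes, hepatocytes and SEC shared 90 fallers, and macrophages and SEC 160 risers and 190 fallers. With array weights SEC had 1278, with 272 and 186 shared risers and fallers with hepatocytes and 201 and 369 with macrophages. With replicate number as a block within each cell type, although no pairing by these numbers was seen, macrophages and SEC shared 45 fallers. Leaving out each array in turn (the lone array of a group is assumed to vary like the other groups) gave 278 to 292 genes in SEC, 14 to 64 fallers shared by hepatocytes and SEC and 29 to 60 by macrophages and SEC, with fewer samples by construction, and 8032 to 8425 genes in hepatocytes and 4358 to 4554 in macrophages. At an unadjusted p in both cell types, a looser criterion, hepatocytes and SEC shared 319 risers and 272 fallers, and macrophages and SEC 216 and 484. With background subtracted the untreated pairs differed in 5207, 5726 and 2510 genes, and shared fallers were 12 for hepatocytes and SEC and 16 for macrophages and SEC; with cyclic loess they were 19 and 33. Genes highest in the untreated cell type are fewer by construction, and their choice on the untreated arrays favours falls. Among them 3716, 2249 and 116 genes and 12, 11 and 8 lists passed in hepatocytes, macrophages and SEC. With an estimated correlation 17 lists passed in SEC, and with fry, which asks another question, 37 in macrophages.

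Under background subtraction and cyclic loess the 35 lists called in hepatocytes all kept their call and direction; in macrophages 20 and 19 of 20 did, and in SEC 24 and 25 of 26, where ribosomal proteins and glycolysis lost their call with background subtracted (adjusted p = 0.0803 and 0.0531) and ribosomal proteins turned up without passing with cyclic loess (0.876). The list lost in macrophages with cyclic loess was oxidative phosphorylation (adjusted p = 0.0509). Lists also gained a call. With background subtracted these were dendritic cell markers in hepatocytes, Notch and Wnt targets in SEC (adjusted p = 0.0113), and 5 in macrophages: oncofetal, P450, bile acid and cholesterol, gluconeogenesis and extracellular matrix genes. With cyclic loess these were the acute phase list in hepatocytes and SEC markers in SEC.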

Other observations

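The genes of highest untreated level in SEC that changed at least 2-fold there were chosen after their values were seen; the lists were fixed before. Ribosomal protein genes rose in hepatocytes, with 20 of 23 measured members higher and 1 lower (adjusted p = 1.62e-05 by camera), such as Rps19 (1.56) and Rps24 (1.41), and in macrophages, with 17 of 23 measured members higher and 1 lower (19 passing adjusted over the list alone) (adjusted p = 2.76e-05), such as Rps6 (0.93). Leukocyte markers rose in the same arrays, with 11 and 13 of 13 neutrophil markers and 9 of 12 T and NK cell markers higher in hepatocytes and macrophages. In SEC limma passed 0 of 23 ribosomal genes (8 adjusted over the list alone; 2 higher and 8 lower at an unadjusted p under 0.05), and the list's call as lower (adjusted p = 0.0451, and adjusted p = 0.203 with an estimated correlation) was lost with background subtracted and turned with cyclic loess. P53 targets and DNA damage genes passed as a list in macrophages, with 9 of 21 measured members higher and 3 lower (15 passing adjusted over the list alone) (adjusted p = 0.00225), such as the stress genes Gadd45b (3.51) and Gadd45a (2.30) and the cell cycle inhibitor Cdkn1a (1.66). They had 3 of 21 measured members higher in SEC (adjusted p = 0.00733, and adjusted p = 0.0611 with an estimated correlation), such as Tnfrsf10b (0.49) and Gadd45b (0.35), and 11 higher and 5 lower of 21 in hepatocytes (adjusted p = 0.118), where Mdm2 (1.04), Plk2 (1.10) and Cdkn1a (0.46) rose and Ei24 (-1.15) and Tnfrsf10b (-1.09) fell. Immediate early and isolation stress genes rose in the same arrays, with 24 of 28 measured members higher in macrophages and in hepatocytes and 8 of 28 in SEC.

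Notch and Wnt targets had 10 of 18 measured members higher and 2 lower in hepatocytes (adjusted p = 0.0215, and adjusted p = 0.0628 with an estimated correlation), such as Sox9 (1.11) and Jag1 (0.99). Sox9 is also on the cholangiocyte marker list, of which 8 of 8 measured members were higher in the same arrays. The Notch and Wnt list did not pass in macrophages (0 higher and 5 lower of 18, adjusted p = 0.392), where Hey1 (-1.38) fell. Nor did it pass in SEC (1 higher and 0 lower of 18 (4 passing adjusted over the list alone), adjusted p = 0.0585), where it passed as higher with background subtracted (adjusted p = 0.0113). Unfolded protein response and ATF4 targets did not pass in hepatocytes (7 higher and 15 lower of 27, adjusted p = 0.191), where the chaperone Calr (-1.73) and Shmt2 (-1.91) fell, in macrophages (9 higher and 5 lower of 27, adjusted p = 0.26), where the phosphatase subunit Ppp1r15a (2.48) rose and Pdia3 (-1.24) fell, or in SEC (1 higher and 1 lower of 27 (5 passing adjusted over the list alone), adjusted p = 0.601), where Hspa5 (0.64) rose. Of the 4132 genes with their highest untreated level in SEC, 3 rose at least 2-fold there, the matrix protein Dpt (2.05 ± 0.05), Esm1 and the calcification inhibitor Mgp (1.60 ± 0.05), and 1, Rab1a, fell. Across genes, arrays of DEN hepatocytes correlated with those of untreated hepatocytes at a mean r of 0.763 over pairs of arrays. With DEN SEC arrays the mean r was 0.787 and with DEN macrophage arrays 0.768. With untreated SEC arrays it was 0.740 and with untreated macrophage arrays 0.765. Arrays of untreated and DEN SEC correlated at a mean r of 0.988, and those of untreated and DEN macrophages at 0.905.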
